A study of Mus musculus with 48 samples.

How the data were processed

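The series profiled kidney RNA from mice that received D-alanine or vehicle, collected at 6 circadian times 4 h apart (CT0, CT4, CT8, CT12, CT16 and CT20). D-alanine is the mirror-image form of the amino acid L-alanine. RNA was extracted from kidney with a column kit and libraries were made with a SMARTER mRNA kit, per the labels' protocols. The labels give neither the dose nor the route, and whether the libraries kept strand is not given in the sources used here. Treatment and time were taken from the label of each of the 48 libraries, which gave 12 groups of 4. The series text describes kidneys from different mice and an experiment run 2 times. The values sit in 2 tables of 24 libraries, each with 2 libraries of every group, and the tables were taken as those 2 runs, which is an inference. Replicates were numbered in the order of the samples, so the numbers pair nothing.

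The authors deposited FPKM values (fragments scaled to gene length and to library total), with 1 column per library for 49585 genes. The genome build is GRCm38 (mm10), per the submitters' processing notes; the aligner, the counter and any filter are not given in the sources used here. Of the gene identifiers, 49326 were found in the GENCODE M21 annotation of that build and 45128 had equal coordinates there. Coordinates below are those of the deposited tables, and each value sums the exons of a gene. FPKM values of low genes moved in steps of 1 fragment. With summed exon lengths from GENCODE M21, 97.0% to 97.7% of the values under 20 fragments in genes with a single transcript came out whole within a tolerance of 0.05, and 92.0% to 93.4% of all such low values did. From these steps the depth was 7626060 to 14403200 fragments per library, with a median of 11601150. The deposited values sum to between 430391 and 541768 per library. The scaling divides every library by its own total, so a few abundant transcripts can lower or raise all others. Genes with near-identical copies or overlapping neighbours share fragments in ways the tables do not show, and this touches Rps2-ps6, Cyp2a5, the pseudogene BC002163 and the overlapping pair mt-Atp8 and mt-Atp6.

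Replicate libraries were compared before use. Every pair differed beyond sampling noise, with a chi-square per gene of at least 5.53. Correlations were 0.945 to 0.987 within a table and 0.901 to 0.971 across tables.

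The tests were fixed before the data were examined. Genes with an FPKM of at least 1 in at least 4 libraries were kept, which left 14922. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a trend, in a model of the 12 groups with the table as an additive term. All p-values from it are two-sided and adjusted by Benjamini-Hochberg at 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Contrasts were D-alanine minus vehicle averaged over the 6 times, the same at each time, the treatment by time interaction (an F test) and the treatment by table interaction. Rhythms were fitted as a 24 h cosine and sine per treatment, with F tests for vehicle, for D-alanine and for the difference between them. For the core clock list, the median amplitude difference and the circular mean of the peak time differences were tested by permuting treatment within time and table (100000 resamples, two-sided; 10000 where 1 library was left out). The share of FPKM taken by mitochondrially encoded genes was tested in the same way; this test was added after the data were seen.

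In advance, 19 pathway lists and 17 lists of cell type markers were fixed. Lists with at least 3 measured members, except the Y-linked genes, were tested with camera at a preset correlation of 0.01, with the correlation estimated as a check, and with fry, and adjusted over the lists of a kind within a comparison. A rhythm enrichment of each list was tested with Fisher's exact test. Named genes followed a rule fixed in advance: for the mean over times the 10 higher and the 10 lower genes with the largest log2 change past the threshold and with the same direction in both tables; for each time the top 5 in each direction; the 10 rhythmic genes with the largest amplitude in vehicle; where fewer than 3 passed, the 5 with the smallest p, named as not past the threshold; any member of the core clock and gluconeogenesis lists; and up to 4 members of each other list with the smallest p. Models named only by a clone or identifier were counted and not named, and some genes that this rule names are not reported here.

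The alternatives set in advance were a pseudocount of 0.1, no filter, rescaling to TPM, quantile normalization, no table term, a table by time term, each table alone, robust moderation, the libraries of 1 time or 1 treatment alone, the times as a factor and leaving out each library. Alternatives chosen after the data were seen were limma voom on the recovered fragments, rescaling without mitochondrial genes, centring each library on its median gene, and as covariates the depth and an inner medulla score (the mean log2 level of 7 genes). The tests of Gene Ontology terms were also chosen then. A count model set in advance was not run. The tests of the mean, CT0, the rhythm in vehicle, differential rhythm and camera were tested on simulated data with changes added to the real means. The rhythm in D-alanine and both interactions were run there only on genes with no such change. The core clock test was run on artificial genes with random peaks and amplitudes and no difference between the tables. The other times, the mitochondrial share, Fisher's test and Gene Ontology were not simulated. For the mean over times, 78% of simulated changes of 0.3 log2 and 98% of those of 1 log2 were called, with 8 of 14722 unchanged genes. The simulated noise was drawn independently for each gene. Real genes vary together, with 25.3% of the variance within time and table on a first component. The simulated numbers of false calls therefore do not carry over to the real data. At CT0 the shares were 20% and 78%. For the rhythm in vehicle, 12% of amplitudes of 0.15 log2 and 92% of those of 0.5 were called; for a rhythm lost in D-alanine, 2% and 82%. In the artificial clock genes a delay of 1 h was recovered as 0.933 h, which need not hold for real clock genes. The other steps were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.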

Results

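RNA was measured in 48 mouse kidney libraries, from animals given D-alanine or vehicle and collected at 6 circadian times, with 4 libraries in each of 12 groups. Each of the 2 deposited tables held 24 libraries, 2 from every group. Depth was 7626060 to 14403200 fragments per library (median 11601150), and 14922 genes passed the filter on low values. All 48 libraries expressed genes of the Y chromosome such as Eif2s3y, a translation factor subunit, at 17.8 ± 2.21 FPKM in vehicle and 17.1 ± 2.25 in D-alanine (SD, n = 24). Values below are FPKM with the SD over libraries unless an SE is named.

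The first question was how the kidney transcriptome cycled in the vehicle animals. Several core clock genes were among those with the largest daily swings. Dbp, a clock output transcription factor, had a 34.0-fold difference between peak and trough on the FPKM + 1 scale and peaked at CT9.71, Ciart, a repressor of the clock, 9.59-fold at CT10.5, and Nr1d1, which encodes the repressor REV-ERB alpha, 7.91-fold at CT7.41. Arntl, which encodes the activator BMAL1, peaked at the opposite phase, at CT22.2, with a 4.33-fold swing, and its partner Npas2 peaked at CT23.4. The period genes Per1, Per2 and Per3 peaked at CT13.0, CT14.9 and CT11.7, and Cry1 at CT18.3. The log2 amplitudes were 2.54 ± 0.12 for Dbp, 1.49 ± 0.13 for Nr1d1, 1.39 ± 0.08 for Per2 and 1.06 ± 0.06 for Arntl (SE). In limma with Benjamini-Hochberg adjustment, 18 of the 19 core clock genes were rhythmic in vehicle, with Rora as the exception (adjusted p = 0.984). The 10 genes of largest amplitude were Dbp, Ciart, Nr1d1, Per2, Nfil3, Mir7027, Mir6375, Per3, Npas2 and Arntl.

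**Figure D1:**
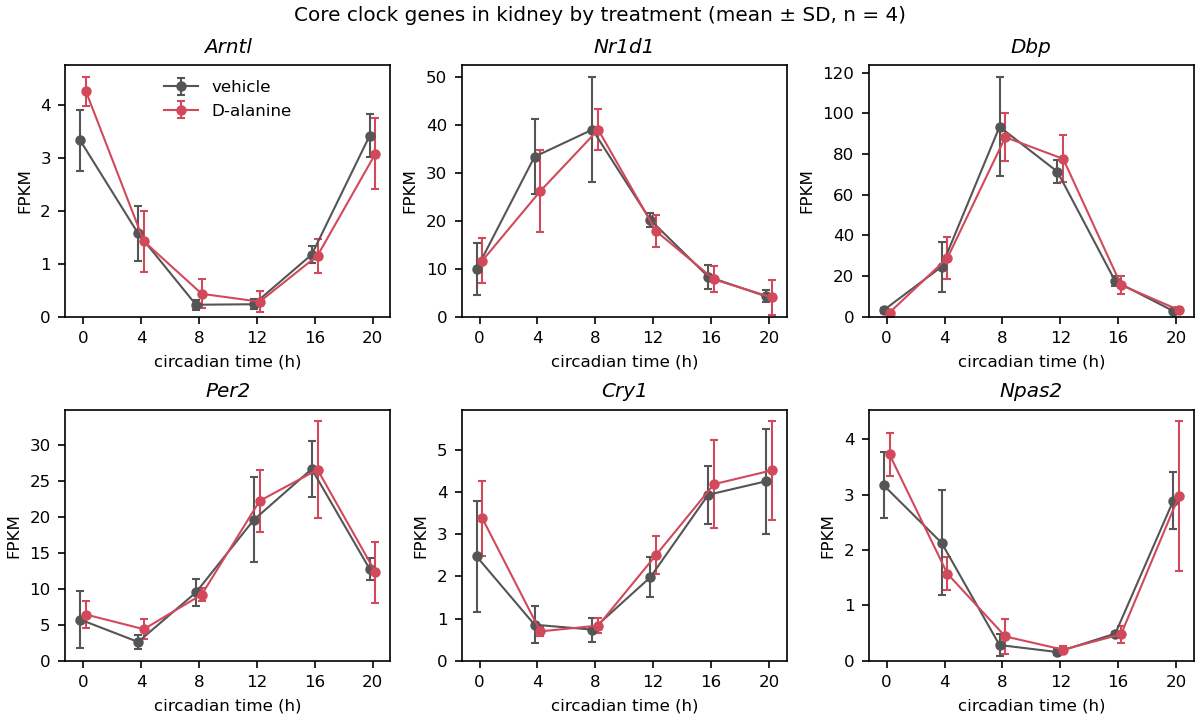
FPKM of 6 core clock genes (vertical axis) against circadian time in hours (horizontal axis), for vehicle in grey and D-alanine in red. Points are means and bars the SD of 4 libraries; Arntl and Npas2 are highest near CT0 and Dbp and Nr1d1 near CT8 in both treatments.

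Across all genes, 1458 were rhythmic in vehicle. The test of other clock-controlled genes gave 10 of 15 as rhythmic, among them Wee1, a cell cycle kinase (peak CT13.1), and Usp2, a deubiquitinase (CT12.7), and 13 when adjusted over the list alone. Glucocorticoid-responsive genes were rhythmic for 5 of 12 members (6 adjusted over the list alone), including Tsc22d3 at CT16.3. No oxidative phosphorylation gene of 18 and no cytosolic ribosomal protein gene of 15 was called rhythmic in vehicle by limma. When both treatments were fitted together, 3736 genes were rhythmic. In Fisher's exact test the rhythmic genes were enriched in the core clock list (adjusted p = 3.99e-09), the clock-controlled list (adjusted p = 0.000118) and the glucocorticoid list (adjusted p = 0.0177), and in the markers of red blood cells and of the distal convoluted tubule (adjusted p = 0.0373 for each). The glucocorticoid list shares Per1 with the core clock list and Fkbp5, Tsc22d3 and Sgk1 with the clock-controlled list. Its enrichment is therefore not separate from theirs. Of 6 red blood cell markers, 4 were rhythmic in vehicle and 0 in D-alanine by limma, and none passed the test of the difference, with 0.0419 as the smallest unadjusted p. Peaks fell most often in the windows centred on CT0 (978), CT8 (818) and CT20 (817), against 413 at CT4, 488 at CT12 and 222 at CT16. The windows of CT20 and CT0 are adjacent, and clustering was not tested. The vehicle count was 266 in the first table alone and 663 in the second table alone, with 12 libraries per treatment in each, and 772 when the times were fitted as a factor, where D-alanine had 1448, so which treatment had more rhythmic genes depended on the model.

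The next comparison asked whether D-alanine altered these rhythms. With both tables pooled, the core clock genes had similar swings and peak times in both treatments, while the peak shifts of the tables were opposed. In D-alanine, Dbp swung 40.6-fold with its peak at CT9.68, Arntl 4.22-fold at CT22.5, Nr1d1 7.79-fold at CT7.25 and Per2 5.15-fold at CT14.7, and again 18 of 19 core clock genes were rhythmic. In total 1238 genes were rhythmic in D-alanine (233 in the first table alone, 725 in the second, 699 in the D-alanine libraries alone and 2404 with the inner medulla score as a covariate), and 736 of them also in vehicle, where independent lists would share 121. Of the 736, 642 (87.2%) peaked within 2 h of their vehicle peak, and the median peak was 0.611 h later in D-alanine. That median pools both tables and was not tested, so a general delay is not shown. Clock-controlled genes were rhythmic for 10 of 15 members (11 adjusted over the list alone) and glucocorticoid genes for 6 of 12 (8 adjusted over the list alone). Of the gluconeogenesis enzymes, 5 of 17 were rhythmic in D-alanine and 2 in vehicle. Pck1, the rate-limiting enzyme of gluconeogenesis, swung 2.40-fold in D-alanine (adjusted p = 5.09e-05 in limma with Benjamini-Hochberg adjustment) and 1.57-fold in vehicle (adjusted p = 0.0628), a difference with an unadjusted p of 0.0700 and an adjusted p of 0.99998 in its own limma test. Adjusted over the list alone, 4 gluconeogenesis enzymes were rhythmic in vehicle and 5 in D-alanine.

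The direct test of differential rhythmicity called 0 genes in limma with Benjamini-Hochberg adjustment (353 at an unadjusted p under 0.05, smallest adjusted p = 0.99998). The smallest p-values, none past the threshold, belonged to the small nucleolar RNA Snord87, the guanylate cyclase subunit Gucy1a3, the basement membrane gene Nid1, the long noncoding RNA Bvht and the lipid-binding protein gene Osbpl9. Nid1 peaked at CT20.8 in vehicle and CT1.19 in D-alanine. The treatment by time interaction, which assumes no curve, also called 0 genes in limma (527 at an unadjusted p under 0.05), and its smallest p-values, not past the threshold, were for Tfap2b, Rbsn, Poc5, Vasp and Psmd11. On simulated data a lost rhythm of 0.25 log2 amplitude was called in 20% of cases and one of 0.5 in 82%. Leaving out 1 library gave 919 to 1593 rhythmic genes in D-alanine and 1148 to 1660 in vehicle.

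As a set, the 18 rhythmic core clock genes differed by -0.02 log2 in median amplitude between D-alanine and vehicle (permutation p = 0.707; 95% of permuted values from -0.09 to 0.09). Their mean peak time differed by 0.0773 h (permutation p = 0.789; 95% from -0.540 to 0.545 h), and 17 of the 18 lay within 1 h. The tables gave opposite directions. In the first table the clock genes peaked 0.858 h later in D-alanine (permutation p = 0.0304), with 17 of 18 later, for example Arntl by 1.03 h. In the second table they peaked 0.797 h earlier (a shift of -0.797 h, permutation p = 0.0408), with 3 of 18 later, so the pooled value near 0 averages 2 opposed values.

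**Figure D2:**
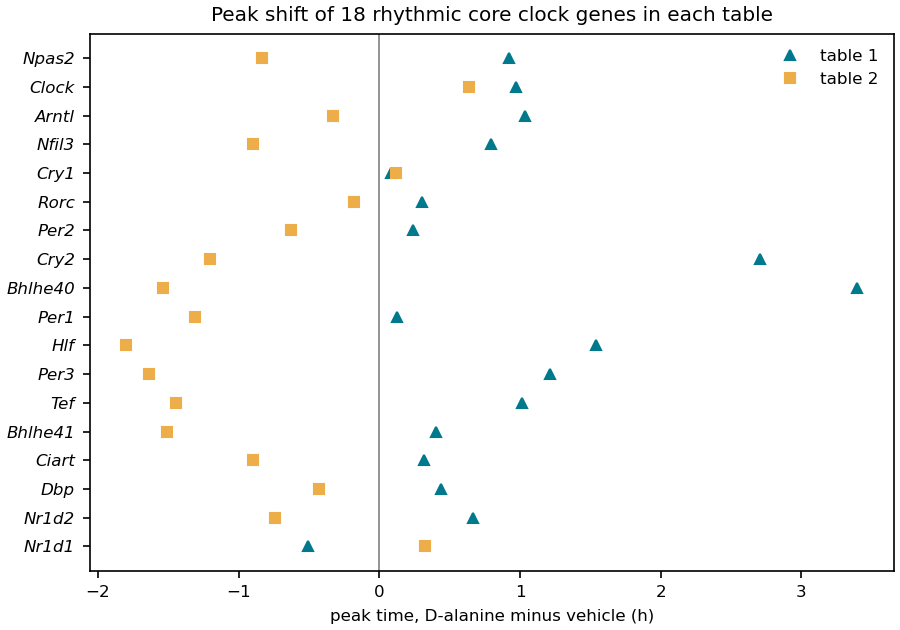
Shift of the peak time with D-alanine in hours (horizontal axis; positive is later) for each of 18 core clock genes (vertical axis), with triangles for the first table and squares for the second table, each from 24 libraries. Shifts lie above 0 for 17 genes in the first table and for 3 genes in the second table; Nr1d1 is the gene of the first table below 0.

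The main treatment comparison averaged D-alanine minus vehicle over the 6 times, with 24 libraries per treatment. D-alanine kidneys had more Ces1g, Mdk and Ier3 RNA and less of several mitochondrially encoded mRNAs. Ces1g, a carboxylesterase (chromosome 8, 93302369 to 93337308), rose from 2.39 ± 1.11 to 6.24 ± 4.02 FPKM, a log2 change of 0.97 ± 0.15 (SE; adjusted p = 0.0025), and was higher in 11 of the 12 pairs of time and table. Mdk, which encodes the growth factor midkine (chromosome 2, 91929805 to 91932297), rose from 10.2 ± 2.03 to 15.9 ± 4.37 FPKM (0.57 ± 0.10, adjusted p = 0.00435), in 12 of 12 pairs. The early response gene Ier3 rose by 0.54 ± 0.11, the peptide hormone gene Adm2 by 0.46 ± 0.09, the cytochrome P450 gene Cyp2a5 by 0.46 ± 0.12 and the orphan nuclear receptor gene Nr4a1 by 0.33 ± 0.09. The matrix gene Prelp (0.35), the complement gene C1ra (0.34) and the vitamin D binding protein gene Gc (0.34) rose as well. Among those that fell were the membrane protein genes Rnf24 (-0.56 ± 0.12, from 27.3 ± 11.6 to 18.3 ± 7.97 FPKM) and Tmem52 (-0.37), the pseudogene BC002163 (-0.34) and Eci3, an enzyme of fatty acid oxidation (-0.17).

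**Figure D3:**
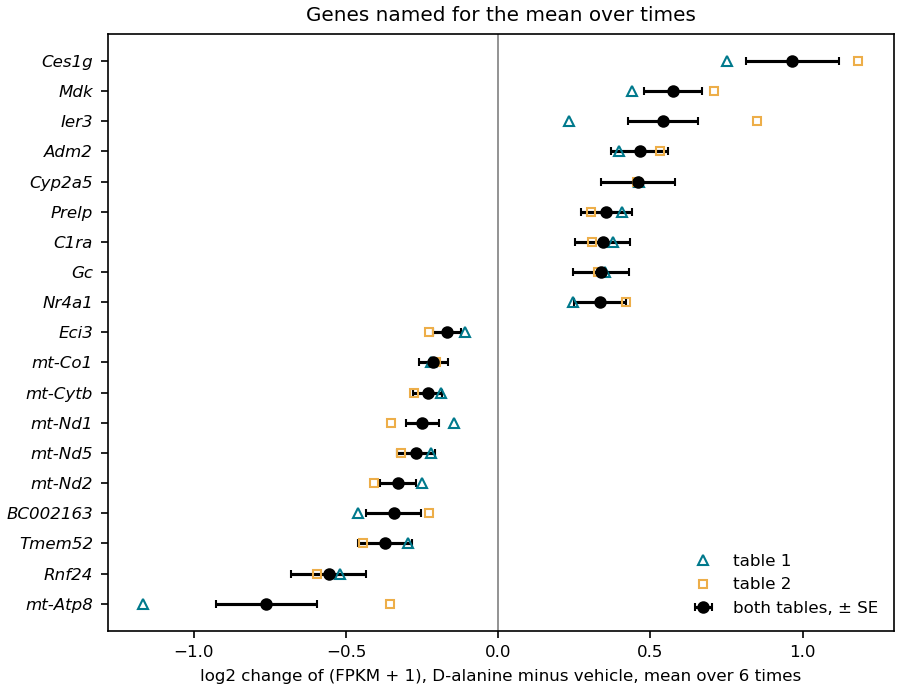
Log2 change of FPKM + 1, D-alanine minus vehicle, averaged over 6 times (horizontal axis) for genes named for this comparison (vertical axis). Black points are both tables with the SE from 48 libraries, triangles the first table and squares the second table; each gene has the same sign in both tables, as the rule for naming it required, and Ces1g is highest at 0.97.

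By limma with Benjamini-Hochberg adjustment, 259 genes passed, 237 higher and 22 lower, and 3064 had an unadjusted p under 0.05. Over all genes the changes of the 2 tables had a Spearman correlation of 0.26 across genes, which are not independent replicates. The balance of higher and lower calls moved with the scaling. Quantile normalization left 14 genes (3 higher, 11 lower), median centring 23 (3 higher, 20 lower) and rescaling without mitochondrial genes 52 (37 higher, 15 lower), while TPM gave 2668 (2638 higher). Ces1g, Mdk, Rnf24, mt-Atp8 and Eci3 still passed after quantile normalization. The first table alone called 0 genes in limma (1187 at an unadjusted p under 0.05) and the second table alone 14, and leaving out 1 library gave between 93 genes (without vehicle CT4 replicate 3) and 631 (without vehicle CT12 replicate 1).

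The mitochondrially encoded mRNAs, which code for subunits of the respiratory chain and ATP synthase, held 6 of the 22 genes called lower. They were not a list fixed in advance and were not tested as a set against other genes. Log2 changes of all 13 were below 0, also with TPM, with median centring and with rescaling without mitochondrial genes; with quantile normalization mt-Cytb turned to 0.03. In limma with Benjamini-Hochberg adjustment 6 fell: mt-Atp8 (-0.76 ± 0.16, adjusted p = 0.0139), mt-Nd2 (-0.33 ± 0.06, adjusted p = 0.00651), mt-Nd5 (-0.27), mt-Nd1 (-0.25), mt-Cytb (-0.23) and mt-Co1 (-0.21). For mt-Nd2 the level went from 19273 ± 8779 to 15709 ± 7893 FPKM. The remaining 7 included mt-Co2 at -0.52 (adjusted p = 0.0826) and mt-Nd6 at -0.06, both picked after their values were seen. Only mt-Atp8 passed after quantile normalization, which gives equal ranks equal values and so can remove changes of the most abundant mRNAs.

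All mitochondrially encoded genes together took 41.4% ± 3.38 of FPKM in vehicle and 37.4% ± 4.33 in D-alanine in the first table, and 19.9% ± 1.95 and 17.0% ± 1.36 in the second table (SD, n = 12). The share was 3.49 points lower with D-alanine (a difference of -3.49, permutation p = 0.00034), and lower in 10 of 12 pairs of time and table. Within tables the difference was -4.05 points in the first table (permutation p = 0.0211) and -2.94 in the second table (permutation p = 0.00117).

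**Figure D4:**
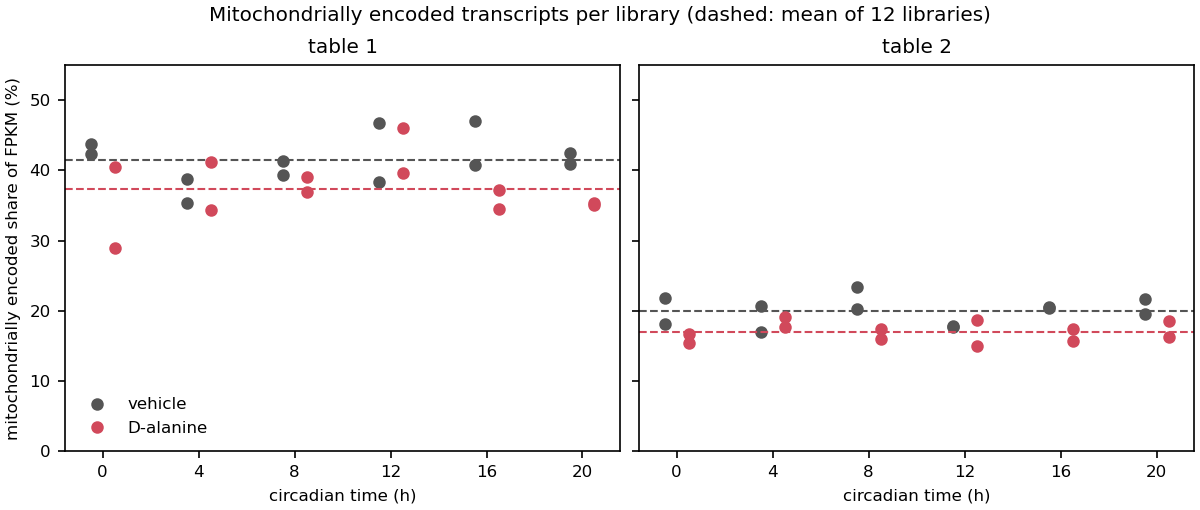
Share of FPKM from mitochondrially encoded genes in percent (vertical axis) for each of the 48 libraries against circadian time in hours (horizontal axis), with the first table on the left and the second table on the right. Points are libraries, vehicle in grey and D-alanine in red; dashed lines are the means of 12 libraries, 41.4% and 37.4% in the first table and 19.9% and 17.0% in the second table.

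Nuclear genes were grouped by lists fixed in advance. Among 12 heat shock and cold-inducible genes, the co-chaperone genes Bag3 (0.27 ± 0.05, 12 of 12 pairs higher) and Dnajb1 (0.25 ± 0.06) rose, and 6 rose when adjusted over the list alone, with Hsph1 at 0.57 and Hspb1 at 0.48. Camera placed this list above other genes (adjusted p = 0.0253), and not so with an estimated correlation (adjusted p = 0.677 with an estimated correlation). The number called over all genes was 2 as deposited, 6 with TPM and 0 with quantile normalization or median centring. Of 13 immediate early genes, Ier3 and Nr4a1 rose (2, and 2 adjusted over the list alone), and Jun stood at 0.22 and Cyr61 at 0.17, not past the threshold. Over all genes this list had 3 higher calls with TPM and 1 with rescaling without mitochondrial genes. With quantile normalization or median centring it had 0. Of 12 amino acid stress genes 0 passed over all genes in limma and 3 rose when adjusted over the list alone, namely Atf4, the transcription factor of that response (0.23), Atf5 (0.33) and Sesn2 (0.17). Of 15 cytosolic ribosomal protein genes, Rplp0 (0.14) and Rpl3 (0.11) rose when adjusted over the list alone. The 18 nuclear genes of oxidative phosphorylation had a median change of 0.00 and a mean of -0.00, with 9 above and 9 below 0, a median of 0.06 with TPM and all 18 below 0 with median centring; camera placed them below other genes (adjusted p = 0.0253; adjusted p = 0.677 with an estimated correlation), against an all-gene median of 0.06.

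Genes of glucose production and of D-amino acid metabolism gave few calls. None of the 17 gluconeogenesis enzymes passed over all genes in limma with Benjamini-Hochberg adjustment. Pck1 stood at 830 ± 308 FPKM in vehicle and 700.1 ± 344 in D-alanine (-0.34 ± 0.10, adjusted p = 0.0629), and was the 1 gene lower when adjusted over the list alone; G6pc, the last enzyme of the pathway, stood at 0.08 ± 0.11 and Fbp1 at 0.01 ± 0.06. Dao, which encodes D-amino acid oxidase, the enzyme that degrades D-alanine, was at 131 ± 28.7 FPKM in vehicle and 135 ± 30.9 in D-alanine (0.04 ± 0.05), and none of 10 D-amino acid handling genes passed either adjustment. Among 11 cholesterol synthesis genes, Hmgcs1 was lower when adjusted over the list alone (-0.17 ± 0.06) and 0 passed over all genes. No member passed either adjustment in the lists of core clock (19 measured), clock-controlled (15), gluconeogenesis and CREB regulator (20), glycolysis (15), glucose transport (11), fatty acid oxidation (19), glucocorticoid response (12), tubular injury (9), oxidative stress (14), interferon (12) and water and salt transport genes (18). Camera called none of these lists (adjusted p from 0.102 to 0.730). Its direction is relative to other genes, so it lay below them although the median was above 0 for the core clock, gluconeogenesis enzyme, glucose transport, D-amino acid, oxidative phosphorylation, tubular injury, oxidative stress, interferon, cholesterol and water and salt lists; fatty acid oxidation had a median of -0.00 and a mean of 0.02. Fry tests whether a list moves on balance one way, without comparing it with other genes, whose median was 0.06. By fry the clock-controlled (adjusted p = 0.0389), gluconeogenesis and CREB regulator (adjusted p = 0.00892), glycolysis (adjusted p = 0.0389) and glucocorticoid lists (adjusted p = 0.0278) lay above 0, as did the immediate early (adjusted p = 0.0380), amino acid stress (adjusted p = 0.0389) and heat shock lists (adjusted p = 0.00298). The medians of these lists stayed above 0 in each scaling tried, down to 0.01 for the CREB regulators with median centring, where 10 of 20 lay below 0. The glucocorticoid list shares Fkbp5, Tsc22d3 and Sgk1 with the clock-controlled list, Dusp1 with the immediate early list and Ddit4 with the amino acid stress list. The calls of these lists are therefore not separate. Sgk1, a kinase of sodium transport, was at 0.56 ± 0.22 and Ldha at 0.09 ± 0.04, neither past the threshold.

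Markers of other cell types were compared in the same way. Of 7 endothelial markers 5 were higher when adjusted over the list alone, among them Pecam1 (7.39 ± 2.41 and 9.92 ± 6.03 FPKM, 0.30 ± 0.12) and Emcn (0.39 ± 0.16), and 0 over all genes in limma (camera adjusted p = 0.0826). Of 5 measured adipose markers 4 were higher when adjusted over the list alone, with Adipoq at 0.0952 ± 0.118 FPKM in vehicle and 0.679 ± 1.11 in D-alanine (camera adjusted p = 0.0863). In every scaling tried, all 7 endothelial and all 5 adipose markers had a change above 0. Adipoq lay near the floor and could pass the filter on low values only through D-alanine libraries. Its direction was thus set by the filter and is no evidence. Camera also placed the proximal tubule, distal convoluted tubule, principal cell, podocyte, macrophage, lymphocyte and red blood cell markers below other genes with medians above 0, none of them called. No marker passed either adjustment for proximal tubule (12 measured), loop of Henle (6), distal convoluted tubule (6), collecting duct principal cell (6), intercalated cell (6), podocyte (6), stroma and smooth muscle (10), macrophage (6), lymphocyte (5), neutrophil (2), red blood cell (6), skeletal muscle (1) and cell cycle (2) lists, nor for the 4 Y-linked genes. The stroma list held Ren1, the renin gene, at -0.32 ± 0.13 and Dcn at 0.30 ± 0.12, neither past the threshold. No adrenal marker passed the filter on low values.

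Each time of day was then compared on its own, with 4 libraries per treatment. At CT0 D-alanine kidneys had higher levels of Axin1, a scaffold of the Wnt pathway (7.01 ± 1.40 and 15.4 ± 10.3 FPKM, 0.88 ± 0.23), Pard6b, a cell polarity gene (8.59 ± 1.93 and 15.9 ± 4.196, 0.81 ± 0.20), Ccdc117 (0.81 ± 0.20) and Rps2-ps6, which resembles a ribosomal protein gene (0.85 ± 0.20). The microRNA gene Mir7668 was listed at 0 in all 4 vehicle libraries and stood at 1.74 ± 1.70 in D-alanine. That level is near the filter's minimum of 1 FPKM and its SD is about as large as its mean, so an absence in vehicle is not shown. Azgp1, a secreted glycoprotein gene, was lower (62.2 ± 19.5 and 41.6 ± 16.5, -0.59 ± 0.15), as was mt-Cytb (-0.46 ± 0.12); with the inner medulla score as a covariate 91 genes were called and with depth 54, all higher, so these lower calls were lost (adjusted p = 0.0723 for Azgp1 and 0.0613 for mt-Cytb with the score). By limma with Benjamini-Hochberg adjustment 170 genes passed, 166 higher and 4 lower (3281 at an unadjusted p under 0.05), and the adjusted p of the named genes lay between 0.0399 and 0.0475. The median change of all genes at CT0 was 0.12 as deposited, 0.25 with TPM (2612 genes called) and -0.00 with quantile normalization (0 called in limma, 2110 at an unadjusted p under 0.05), so the calls at CT0 are relative to these medians. Of all libraries, D-alanine CT0 replicate 2 had the highest inner medulla score (3.11), and it had the lowest mitochondrial share of the first table (28.9%). The count was 0 without vehicle CT0 replicate 2 or without D-alanine CT0 replicate 2, 1 without vehicle CT0 replicate 4, 18 without D-alanine CT0 replicate 3, 521 without D-alanine CT0 replicate 1, 741 without D-alanine CT0 replicate 4 and 1247 without vehicle CT0 replicate 1.

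At the other times limma with Benjamini-Hochberg adjustment called 0 genes, with 381 at CT4, 2215 at CT8, 338 at CT12, 708 at CT16 and 384 at CT20 at an unadjusted p under 0.05. The genes with the smallest p, none past the threshold, were at CT4 Tdp1, Prkag3, Nr4a1, Poc5 and Bco2. At CT8 they were the calcium channel gene Orai3 (6.81 ± 1.65 and 9.89 ± 2.43 FPKM, 0.48 ± 0.10, adjusted p = 0.272), Recql, Fam98a, Cadm1 and Coro1c. CT12 gave Nr4a1 (1.52 ± 0.545 and 3.28 ± 0.576 FPKM), the clock-linked deadenylase gene Noct, Hoxd8 and Eif3s6-ps2. CT16 gave Mdk (8.79 ± 2.09 and 18.3 ± 4.803 FPKM), Glmp, Adm2, Hist1h4i and Epn1, and CT20 gave Plk3, a stress-responsive kinase (3.51 ± 1.33 and 7.95 ± 3.43 FPKM, adjusted p = 0.435), Clec3b, Zbtb16, Armc12 and Gsta3. Because the interaction test called 0 genes, a difference between CT0 and other times was not shown.

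The lists at single times gave camera calls at the preset correlation for 2 lists at CT0, 0 at CT4, 12 at CT8, 4 at CT12, 10 at CT16 and 4 at CT20, and for 0 lists at any time with an estimated correlation. The smallest camera p at CT8 was that of oxidative phosphorylation, with 17 of 18 genes below 0 and a median of -0.10 (camera adjusted p = 1e-07; adjusted p = 0.245 with an estimated correlation). At CT16 the same list lay the other way, with 17 of 18 above 0 and a median of 0.08, not called (camera adjusted p = 0.106). Camera placed proximal tubule markers below other genes at CT0 (median -0.08, adjusted p = 0.0188; adjusted p = 0.712 with an estimated correlation) and CT8 (median -0.01, adjusted p = 0.0228; adjusted p = 0.721 with an estimated correlation), and above at CT16 (12 of 12 above 0, median 0.24, adjusted p = 0.0296; adjusted p = 0.603 with an estimated correlation). Immediate early genes at CT16 had 3 of 13 above 0 and a median of -0.18 (camera adjusted p = 0.00279; adjusted p = 0.316 with an estimated correlation), against 12 of 13 above 0 for the mean over times; Nr4a1 was at 2.75 ± 0.490 FPKM in vehicle and 1.80 ± 0.694 in D-alanine there, not past the threshold. Heat shock genes at CT8 had 11 of 12 above 0 and a median of 0.34 (camera adjusted p = 0.0118; adjusted p = 0.258 with an estimated correlation), with 6 higher when adjusted over the list alone; Hsph1 was at 8.91 ± 1.55 FPKM in vehicle and 32.2 ± 19.5 in D-alanine. Endothelial markers at CT8 were all above 0 with a median of 0.78 and 6 of 7 higher when adjusted over the list alone (camera adjusted p = 0.000308; adjusted p = 0.491 with an estimated correlation), with Emcn at 7.61 ± 0.562 and 20.995 ± 11.3 FPKM. Adipose markers at CT8 had a median of 0.88 (camera adjusted p = 0.0228; adjusted p = 0.665 with an estimated correlation) and stroma markers 0.39, not called. Fry called the heat shock (adjusted p = 0.0275) and endothelial lists (adjusted p = 0.0233) at CT8. At CT0 fry called the CREB regulator (adjusted p = 0.00229), heat shock (adjusted p = 0.0224) and water and salt lists (adjusted p = 0.0288). Camera, which compares with other genes, called none of these at CT0 (adjusted p = 0.241, 0.204 and 0.595), where the all-gene median was 0.12. All 6 loop of Henle markers also lay above 0 at CT0 (median 0.47), not called (fry adjusted p = 0.153).

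The CT8 libraries also differed in a score of 7 inner medulla genes, such as Slc14a2 and Aqp4, which was looked at after the data were seen. In the first table it was -1.06 and -0.91 in vehicle and 2.02 and 1.64 in D-alanine, and in the second table -0.56 and -0.55 in vehicle and -1.95 and 0.44 in D-alanine. By table, the CT8 medians were 0.59 and 0.13 for heat shock genes, 1.19 and 0.36 for endothelial markers, 1.74 and 0.08 for adipose markers and 0.62 and 0.19 for stroma markers. Oxidative phosphorylation genes had medians of -0.13 and -0.04, and principal cell markers 0.92 and -0.13. With the score as a covariate the medians at CT8 were 0.23 for heat shock genes, 0.31 for endothelial, 0.58 for adipose and 0.32 for stroma markers and -0.05 for oxidative phosphorylation genes, while principal cell markers turned from 0.44 to -0.10 and proximal tubule markers from -0.01 to 0.22. With it 10 lists were called at CT8 in place of 12, and genes at an unadjusted p under 0.05 fell from 2215 to 1030.

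The last comparison asked whether the treatment difference was alike in the 2 tables. Per gene, the treatment by table interaction called 0 genes in limma with Benjamini-Hochberg adjustment (573 at an unadjusted p under 0.05, smallest adjusted p = 0.987). Its smallest p-values, not past the threshold, belonged to the ribonucleotide reductase gene Rrm2, Ngdn, Lpar6, the elastic fibre gene Fbln5 and the potassium channel gene Kcnq1.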

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

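The tests of scaling for the mitochondrial mRNAs and for the share of higher genes, and the test of the clock shift between the tables, were chosen only after the results were seen; so was the list of inner medulla genes.

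The inner medulla score, the mean log2 level of 7 genes such as Slc14a2 and Aqp4, was far above the other libraries of its group in vehicle CT0 replicate 1, at 2.1566. It was the only one in 48 checks, of 12 groups for 4 measures each, where chance alone would give about 1 in 20. Each group mixes both tables, so the checks of the mitochondrial share (39.4% and 18.4% by table) could hardly flag a library. The 1 in 20 therefore does not hold for all checks, and the flag is not taken as more than chance. Without that library the mean over times called 463 genes in place of 259, and CT0 called 1247 in place of 170.

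The shift of the core clock peaks with D-alanine differed between the tables by 1.6551 h (permutation p = 0.00223). Arntl, Dbp and Per2 peaked later with D-alanine in the first table and earlier in the second, while Nr1d1 went the other way in both. A single library as the whole source was argued against, since the highest permutation p without 1 library was 0.0116, without D-alanine CT4 replicate 1, and the scaling likewise, since p was 0.00692 after quantile normalization. The tables are not groups of the design, so no biological explanation was tested, and a difference between the 2 runs in the handling of animals or time stays open.

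The mitochondrially encoded mRNAs, among them mt-Atp8 and mt-Nd2, were lower with D-alanine, by a mean of -0.35 ± 0.08 log2 (SE) over 13 mRNAs. A few other genes taking the signal would lower the remaining genes alike, but the median change of the other genes was 0.06. That argues against this as the whole cause. The mean of the mRNAs relative to the median gene was -0.42 ± 0.09. It follows from the values already seen, so it adds no separate evidence. The mean was -0.33 ± 0.08 with the inner medulla score as a covariate and -0.35 ± 0.09 with depth as a covariate, which argues against those. The size also moved with the scaling. After quantile normalization the mean was -0.24 ± 0.06, the median went from -0.27 to -0.10 and the calls from 6 to 1. There mt-Nd2 was at -0.09 and mt-Cytb at 0.03, while mt-Atp8 and uncalled members such as mt-Atp6 (-0.50) carried the mean. That scaling gives genes of equal rank the same value in every library, so it can remove a change of the most abundant mRNAs. For those, such as mt-Cytb (35471 FPKM in vehicle), it cannot decide the size. An effect of the treatment on mitochondrial transcripts may be behind the lower levels, as a hypothesis only. RNA quality and the yield of mitochondrial RNA stay open as untested.

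Most genes called for the mean over times were higher with D-alanine (91.5%), as for Ces1g and Mdk. After centring each library on its median gene 13.043% of the called genes were higher, but the centring lowers every change by about 0.07 log2, more than the median SE of the genes called higher (0.04), so it sets the balance itself and decides nothing. The values are relative to each library's total, which keeps the scaling open as a source of the excess. For the genes called higher, inner medulla content as scored was argued against as the whole cause. Their median change kept 91.9% of its size with the score as a covariate (0.17 and 0.16). These genes were picked in the fit without the score, which favours such a result. Over all genes the median change went from 0.056 to 0.045 with the score. Of the genes called with the score in the fit, 377 were higher and 24 lower.

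Other splits of the libraries were tested as a guard against chance. For the mean over times 1 of 100 splits called as many genes as the 259 of the real one, which was that split itself. The highest other called 1. This argues against chance for the values as deposited, as far as 100 splits can show. The rhythm counts also stood alone, with 1 of 100 shuffles in vehicle (1458 against a highest other of 350) and 1 of 100 in D-alanine (1238 against 60). At CT0, 3 of the 35 splits called as many as the 170 of the real one, and the highest other called 2583. The libraries of CT0 thus have a structure beyond treatment. These 35 splits ignored the table, whereas the real treatment was balanced over both tables. The split that follows the tables called 192. Such splits are no fair measure of chance for the real one, so chance at CT0 was not excluded. At CT4, CT8, CT12, CT16 and CT20 the real count was 0, which all 35 of 35 splits reach by definition, so this says nothing about chance. The highest others were 1, 1, 1, 1 and 0. For the treatment by time interaction, differential rhythmicity and the treatment by table interaction 100 of 100 splits likewise reached the real 0 by definition. The highest others were 2, 5 and 1.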

How the results depend on the processing

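Limma voom, rescaling without mitochondrial genes, median centring, the inner medulla and depth covariates, and the alternatives of the mitochondrial share were tests chosen only after the results were seen. Main counts were 259 genes for the mean, 170 at CT0, and 1458 and 1238 rhythmic in vehicle and D-alanine. Except where a construction is named, the cause was not tested.

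A pseudocount of 0.1 gave 51 genes at CT0. No filter gave 153 for the mean, 14 at CT0 and 1 at CT12 with more genes tested. TPM gave 2668 and 2612, with an all-gene median of 0.11 and 0.25 against 0.06 and 0.12 as deposited. Quantile normalization gave 14 (3 higher, 11 lower; 12 shared) and 0 at CT0 (2110 at an unadjusted p under 0.05 in limma, given below as unadjusted), and turned mt-Cytb to 0.0277. Median centring gave 23 (3 higher, 20 lower; 19 shared) and 0 at CT0 (2289 unadjusted), with a median of -0.04 there. Rescaling without mitochondrial genes gave 52 (37 higher, 15 lower) and 7, and turned the clock peak difference to -0.0248 h. The inner medulla covariate gave 401 (255 shared), 91 at CT0 and 2404 rhythmic in D-alanine (1692 vehicle), and the depth covariate 54 at CT0. Voom gave 248 (238 shared) and 180.

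No table term gave 17 for the mean, 0 at CT0 (1993 unadjusted), 599 rhythmic in vehicle and 494 in D-alanine. The first table alone, with fewer libraries, gave 0 for the mean (1187 unadjusted), 2 at CT0, 1 at CT12, 2 for the treatment by time interaction, 266 and 233 rhythmic genes, and a clock peak difference of 0.858 h. The second alone gave 14, 0 at CT0 (1652 unadjusted), 1 at CT4, 663 and 725 rhythmic genes, a clock peak difference of -0.797 h and an amplitude difference of 0.0479. The 8 libraries of CT0 alone gave 0 (1912 unadjusted), the times as a factor 772 and 1448 rhythmic genes in vehicle and D-alanine, and each treatment's libraries alone 1746 and 699.

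With camera's correlation estimated, 0 lists were called for the mean, CT0, CT8, CT12, CT16 and CT20, in place of 2, 2, 12, 4, 10 and 4. For the mean, quantile normalization gave 6 lists, all higher, so the call of oxidative phosphorylation was lost; rescaling without mitochondrial genes gave 4 (3 higher) and the inner medulla covariate 4 (2 higher). At CT4 that covariate gave 1. With quantile normalization the lists at CT0 went from 2 lower to 2 higher, and at CT8 from 3 higher and 9 lower to 6 and 2. Of 79 values for named genes and lists, 8 lost the threshold with a pseudocount of 0.1 and 22 with quantile normalization (1 reversed). Without mitochondrial genes 16 did, and with the inner medulla covariate 5. In the first table alone 28 did, in the second 26 (lists and table interaction not run). Genes named as not past the threshold could not lose it. Ces1g and Mdk passed with quantile normalization and in the second table alone, not in the first.

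Leaving out 1 library gave 93 to 631 genes for the mean, 0 to 1247 at CT0, 0 to 1 at CT12 (1 without D-alanine CT12 replicate 2), and 0 to 0 at CT4, CT8, CT16 and CT20 and for both interactions and differential rhythmicity. Rhythmic genes ranged from 1148 to 1660 in vehicle and 919 to 1593 in D-alanine, the clock peak difference from -0.0520 to 0.194 h, the amplitude difference from -0.0301 to 0.00552 and the mitochondrial share difference from -3.98 to -3.01 points. The mean count was 631 without vehicle CT12 replicate 1, 579 without D-alanine CT20 replicate 1, 463 without vehicle CT0 replicate 1, and 432 and 424 without D-alanine CT0 replicates 4 and 1. It was 162 without D-alanine CT8 replicate 2, 156 without vehicle CT20 replicate 2, 155 without D-alanine CT4 replicate 3, 149 without D-alanine CT20 replicate 2 or CT16 replicate 3, 139 without vehicle CT0 replicate 4, 124 without D-alanine CT12 replicate 4, 116 and 103 without vehicle CT16 and CT12 replicates 2, and 93 without vehicle CT4 replicate 3. The CT0 count was 1247, 0 and 1 without vehicle CT0 replicates 1, 2 and 4, and 521, 0, 18 and 741 without D-alanine CT0 replicates 1, 2, 3 and 4. Libraries of other times enter CT0 through the shared spread: it was 263 without D-alanine CT20 replicate 1, and between 52 and 113 without any 1 of these: vehicle CT4 replicates 1, 2 and 4, CT8 replicates 1, 2, 3 and 4, CT12 replicates 3 and 4, CT16 replicates 1 and 3, CT20 replicates 1, 2, 3 and 4; D-alanine CT4 replicates 3 and 4, CT8 replicates 1, 2, 3 and 4, CT12 replicates 3 and 4, and CT16 replicate 4.

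The count model set in advance was not run, since the values are FPKM and their steps depend on assumed gene lengths. Voom, on fragments recovered with those same lengths, was added afterwards. No analysis paired by replicate was possible because the labels give no replicate numbers; a table by time term gave 311 genes for the mean. At 7626060 to 14403200 fragments and 4 libraries per group, simulated changes of 0.3 log2 at CT0 were called in 20% of cases.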

Other observations

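The tests of Gene Ontology terms and the inner medulla covariate were chosen only after the results were seen.

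Terms passed for the genes peaking near CT0, CT8 and CT20, and none for those peaking near CT4, CT12 and CT16. Among genes peaking near CT8, 38 of 260 transmembrane transport genes were found where 14.6 were expected (hypergeometric adjusted p = 9.77e-05), for example Slc5a6 and Slc12a7. Near CT0, 22 of 96 extracellular matrix organization genes (7.46 expected, adjusted p = 0.00617), such as Col4a1 and Npnt, and 43 of 274 cell adhesion genes (21.3 expected, adjusted p = 0.00645) peaked. Over all peak times, 34 of 62 genes of circadian regulation of gene expression were rhythmic (17.2 expected, adjusted p = 0.0122), and 45 of 96 of extracellular matrix organization (26.6 expected, adjusted p = 0.0470). Near CT20, 10 of 27 genes of microtubule-based processes peaked (1.75 expected, adjusted p = 0.00764), among them Dynll1 and Tubb2a. Among the genes higher with D-alanine, 5 of 16 stress fiber assembly genes were found (0.311 expected, adjusted p = 0.0193). The tests used 10662 annotated genes (71.5% of those tested) and 2005 terms, with adjustment within each of 8 gene sets.

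The heat shock list, with Bag3 and Dnajb1, had a mean change of 0.27 ± 0.09 log2 (SE), and 0.20 ± 0.05 with the inner medulla score as a covariate. Its source was listed for weighing, and the clock shift between the tables took its place before any test of it was run. The inner medulla score differed between treatments by 0.31 ± 0.31 (SE). Of its 7 genes 2 are in another list (Aqp4 in water and salt transport and Slc5a3 in glucose transport), and none in the heat shock list. None of the 7 genes passed in limma, although all but Aqp4 (-0.08) had a change above 0, from 0.14 for Slc5a3 to 0.57 for Akr1b3. Those genes were listed after the first component of the variation within groups had been looked at, so the tie between that component and the score is circular and nothing is drawn from it. The tables differed in mitochondrial share, with 39.4% ± 4.32 of FPKM in the first and 18.4% ± 2.23 in the second (SD, n = 24).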
